A study of Homo sapiens with 6 samples.

How the data were processed

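RNA was sequenced from CFPAC and KP3 cells after control, NEK6 or NEK7 siRNA, with 1 library for each line and siRNA and no replicates. The control libraries carry control siRNA in their titles and WT in their treatment tag, and they were taken as control siRNA. Per the labels' protocols, libraries were made from 5 ug of total RNA with oligo(dT) Dynabeads. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR were used, with no role or order given. The authors deposited a count for each gene and library, whole numbers without normalization. The FPKM values of the same genes, also deposited by the authors, are scaled to transcript length and library size, per the file headers. The genome build is not given in the sources used here. Of 33097 gene records, 32211 ids are in GENCODE v29, and 32205 of them (99.98%) overlap that annotation (GRCh38) on the same chromosome and strand. There were 1971 gene names on more than 1 record, and records were kept apart by id.

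Before the data were examined, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed. That design assumed FPKM with limma, or edgeR if counts were present. The table holds counts, so edgeR was used for the tests of single genes and limma became an alternative. Genes with an FPKM of at least 1 in at least 1 library were tested, 14582 in all. edgeR 4.0.16 (R 4.3.3) fitted counts with TMM normalization, cell line and siRNA as factors, and quasi-likelihood F tests with 2 residual degrees of freedom. p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The common dispersion was 0.0685, a biological coefficient of variation of 26.2%. Cell line was the block in the siRNA contrasts, since both lines got each siRNA.

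Within a line, differences were taken of log2(FPKM + 1) and no test was made. Genes changed at least 1.5-fold the same way in both lines were counted beside the number that independent lists give. The siRNA contrasts against control share control libraries, so unchanged groups were simulated 20 times for each line. Percent of target left came with 95% intervals from the counting errors of the log ratio. Folds for genes at 0 counts in a line used a floor of 3 counts per library. Of 32 gene lists, 31 had at least 3 tested members and were tested with camera (limma 3.58.1) on log2(FPKM + 1), with a preset correlation of 0.01 and with an estimated correlation, adjusted by Benjamini-Hochberg over the lists of a contrast. Members of lists with few counts in a line were left out of the printed folds. Some list members are not reported here.

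The rule for named genes took NEK6, NEK7, NEK9, NLRP3, PYCARD, CASP1, CASP4, GSDMD, GSDME, IL1B and IL18 always. For each siRNA against control it took the 10 genes most increased and the 10 most decreased by the smaller of both lines' differences, for NEK7 against NEK6 siRNA 5 and 5, and for the lines the 12 higher and 12 lower with the largest difference among those that passed. It also took the 3 most increased and 3 most decreased genes within each line and siRNA, and up to 4 members of each list described with the largest mean difference. Names given by clone were skipped. Values of other contrasts and libraries given beside these genes, and NEK4, were added after their values were seen.

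Alternatives were a pseudocount of 0.1, no filter and a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, limma without trend, no block, an estimated correlation, the control libraries alone for the lines, and each library left out. Added after seeing the data were limma itself, DESeq2 1.42.0, DESeq2 size factors, edgeR's filterByExpr, protein-coding genes alone and camera on the counts. For seed matches, 7-base words were searched in the 3' UTRs of 11420 genes, while 3162 tested genes without a usable 3' UTR of at least 50 bases were not searched. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

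The tests were tried on simulated counts with 200 changed genes in each of 3 runs over 14582 genes. For NEK7 siRNA against control, edgeR found 7 of 201 genes changed 1.5-fold, 65 of 201 changed 2-fold and 146 of 198 changed 4-fold, with 4 false calls, and DESeq2 found 8, 77 and 147 with 26 false calls. For CFPAC against KP3, edgeR found 12, 105 and 164 with 6 false calls, and DESeq2 22, 131 and 172 with 67 false calls. For NEK7 siRNA, camera found 3 of 3 lists shifted by 0.3 log2 with 0 other calls, and the search of 11420 genes found 5 of 5 words planted with a shift of -0.15 in CFPAC. The simulated counts were drawn independently for each gene. The 0 other calls thus cannot show how often camera falsely calls lists whose genes vary together.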

Results

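Gene expression was profiled by RNA sequencing in CFPAC and KP3, a pair of established human pancreatic cancer cell lines. Each line was sequenced after a control siRNA, an siRNA against NEK6 and an siRNA against NEK7, which made 6 libraries, 1 for each line and siRNA. The series title concerns NEK7, pyroptosis and the inflammasome in pancreatic cancer, and its design text names a comparison of the lines. NEK6 and NEK7 are related mitotic kinases, and NEK7 also binds the inflammasome sensor NLRP3. Library totals ran from 59478910 to 66067379 counts, and 14582 of 33097 genes reached an FPKM of 1 in at least 1 library. Mitochondrially encoded genes took 17.9%, 15.5% and 15.2% of the counts in the CFPAC control, NEK6 siRNA and NEK7 siRNA libraries, and 11.8%, 13.6% and 11.4% in those of KP3. Across genes, Pearson's r of log2(FPKM + 1) was 0.968 to 0.974 between libraries of the same line and 0.777 to 0.792 between lines. No condition had a replicate library. Differences within a line therefore have no replicate check and no error. For the siRNA contrasts the p-values measure how far the mean change exceeds the part of the siRNA effects that differs between the lines. For the line contrast they measure how far the line difference exceeds its spread over the 3 siRNA conditions. With 2 residual degrees of freedom, even a change alike in both lines can miss the threshold. Intervals and floors cover counting error only.

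The siRNA targets were examined first. NEK6 (ENSG00000119408, chromosome 9, 124257606 to 124353307) had 15.2 FPKM in CFPAC with control siRNA and 4.09 with NEK6 siRNA, which left 26.9% of its level (95% interval 25.3 to 28.5 from counting error). In KP3 it had 21.3 FPKM with control siRNA and 6.98 with NEK6 siRNA, which left 32.8% (31.3 to 34.4). NEK7 (ENSG00000151414, chromosome 1, 198156994 to 198322420) had 14.8 FPKM in CFPAC with control siRNA and 2.40 with NEK7 siRNA, which left 16.2% (15.1 to 17.3). In KP3 it had 14.7 FPKM with control siRNA and 5.79 with NEK7 siRNA, which left 39.5% (37.7 to 41.4). With the siRNA against the other kinase, NEK6 stood at 14.2 FPKM in CFPAC and 22.4 in KP3, and NEK7 at 18 and 12.4. Each library thus had the low target that its label names. Over both lines, the edgeR quasi-likelihood test gave a log2 fold change of -1.75 (SE 0.13) for NEK6 with NEK6 siRNA and of -1.93 (SE 0.45) for NEK7 with NEK7 siRNA. Their Benjamini-Hochberg adjusted p-values over all genes were 0.181 and 0.492, neither past the threshold, whereas DESeq2 gave adjusted p-values of 1.84e-25 for NEK6 and 0.0019 for NEK7. For NEK7 the edgeR log2 fold change was -1.24 without the CFPAC and -2.81 without the KP3 NEK7 siRNA library.

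**Figure D1:**
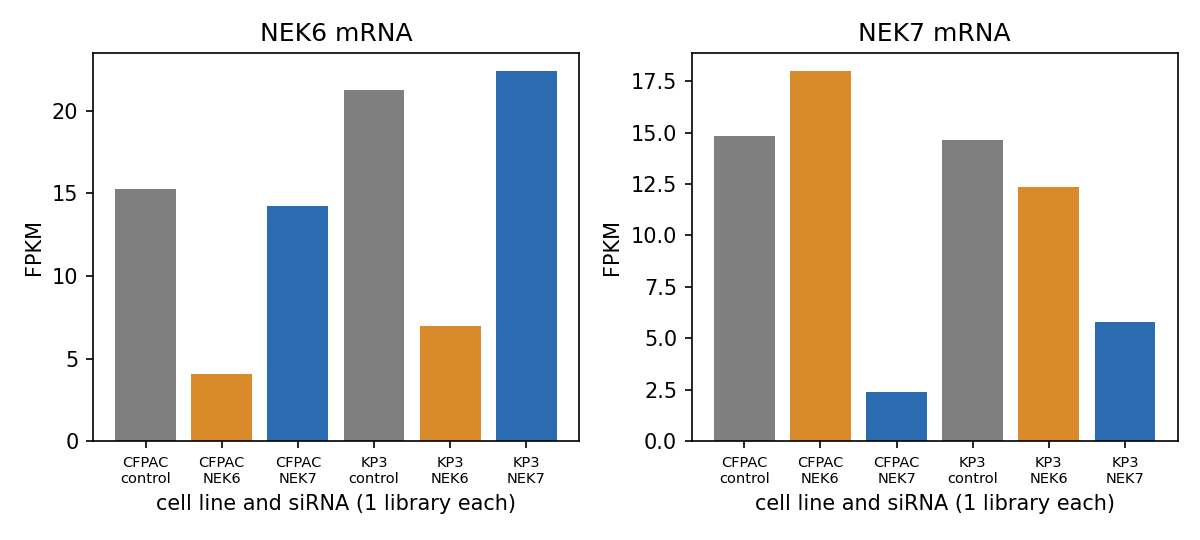
NEK6 and NEK7 mRNA as FPKM (vertical axis) in each of the 6 libraries, by cell line and siRNA, with 1 bar per library. NEK6 was lowest with NEK6 siRNA (4.09 in CFPAC, 6.98 in KP3) and NEK7 lowest with NEK7 siRNA (2.40 and 5.79).

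The comparison of NEK7 siRNA with control siRNA asked which genes moved with loss of NEK7 in both lines. MDM4, an inhibitor of p53, was among the lowest genes, with log2 differences of -1.39 in CFPAC and -1.70 in KP3 (edgeR log2 fold change -3.03, SE 0.20, Benjamini-Hochberg adjusted p = 0.173). Its 3' UTR holds 1 site of a 7-base word that is taken up below as a possible seed match of the NEK7 siRNA. GPD1L, a glycerol-3-phosphate dehydrogenase-like protein, was lower by -1.20 and -1.39 (-2.16, SE 0.19, adjusted p = 0.173 by edgeR), and SCAMP1, a carrier protein of secretory membranes, by -1.18 and -1.13 (-1.40, SE 0.12, adjusted p = 0.173 by edgeR). KCTD20 was lower by -1.20 and -1.15. Of the genes that were higher, HRH1, the histamine H1 receptor, went from 25 to 1734 counts in CFPAC and from 21 to 952 in KP3 (log2 differences 2.28 and 1.60, edgeR log2 fold change 5.74, SE 0.53, adjusted p = 0.173). The tyrosine kinase YES1 was higher by 1.92 and 1.67, the syndecan-binding adaptor SDCBP by 1.46 and 1.47, the kinase HIPK1 by 1.34 and 1.42, and PAQR4 by 1.75 and 1.77. The developmental transcription factor HOXA3 was higher by 1.48 and 1.31, the scaffold DLG3 by 1.65 and 1.3, and DCAF17 by 1.28 and 1.55.

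Most of the genes that were higher were also higher with NEK6 siRNA in at least 1 line. Both siRNAs share the control library of a line, which by itself makes their differences alike. In simulated unchanged groups it gave r = 0.499 in CFPAC and 0.498 in KP3. HIPK1 had 1201 counts in CFPAC with control siRNA, 3996 with NEK6 siRNA and 4323 with NEK7 siRNA, and KCTD20 had 2880, 937 and 1094. HRH1 had 446 counts with NEK6 siRNA in CFPAC and 690 in KP3, and DLG3 had 2120 counts with control and 7069 with NEK6 siRNA in CFPAC and 1119 and 2736 in KP3. In CFPAC PAQR4 went from 970 to 3840 counts with NEK6 siRNA and DCAF17 from 216 to 1088, and in KP3 YES1 from 1708 to 5275, SDCBP from 5958 to 14090 and HOXA3 from 264 to 837. In the other line they moved less, PAQR4 from 1033 to 984 and DCAF17 from 477 to 670 in KP3. There YES1 went from 2824 to 3760, SDCBP from 7982 to 11315 and HOXA3 from 381 to 386 in CFPAC. Of the genes that were lower, MDM4 had -0.15 and 0.25 with NEK6 siRNA, GPD1L -0.28 and -0.20 and SCAMP1 0.08 and -0.06. The ribosomal protein pseudogene RPS26P19 was higher by 3.76 in CFPAC and 3.33 in KP3, and its reads cannot be told apart from those of its parent gene with certainty. The antisense gene MYG1-AS1 was lower by -1.25 and -1.19, which is as uncertain, since the sources used here do not say whether counting used strand. The small RNA SNORD14D was higher by 1.52 and 1.81, while RN7SL657P was lower by -1.87 in both lines, SNORA6 by -1.89 and -1.71, RNA5SP383 by -1.36 and -1.71 and SNORD87 by -3.39 and -1.32. These small RNAs rested on few counts, for example 64 against 1 for SNORD87 in CFPAC, and several lie within other genes. No gene passed edgeR's adjusted threshold of 0.05 in this contrast, where 1372 of 14582 genes had an unadjusted p under 0.05 and chance gives 729.1. limma on log2(FPKM + 1) also called 0 genes, and DESeq2 called 369, of which 193 were higher and 176 lower.

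Among the gene lists fixed beforehand, 6 of 31 were shifted with NEK7 siRNA by camera with its preset correlation (Benjamini-Hochberg over the lists), and none kept its call with an estimated correlation. That setting rests on the 2 residual degrees of freedom and could hardly call any list, so it cannot decide between them. For hypoxia and glycolysis genes its correlation, -0.027, lay below the preset 0.01, yet the unadjusted camera p rose from 1.87e-05 to 0.039. The estimated correlation was 0.871 for mitochondrially encoded, 0.419 for cytoplasmic ribosomal protein and 0.264 for interferon-stimulated genes, far above the preset. The preset p-values of these lists may therefore be too small. Hypoxia and glycolysis genes were lower as a group, with median log2 differences of -0.15 in CFPAC and -0.20 in KP3 (camera adjusted p = 0.00029, and adjusted p = 0.816 with an estimated correlation), and 18 of 33 members were lower in both lines. They included the glycolytic enzymes ALDOA (-1.04 and -0.45), LDHA (-0.50 and -0.48) and ENO2 (-0.24 and -0.94) and the hypoxia-induced ANGPTL4 (-0.32 and -0.77). Interferon-stimulated genes were higher as a group, with medians of 0.09 and 0.37 (camera adjusted p = 0.00314, and adjusted p = 0.816 with an estimated correlation), and 21 of 40 were higher in both lines. Among them IFI27 had 1.17 and 0.62, IFITM1 0.72 and 0.48 and IFI44L 0.25 and 0.93, whereas the chemokine CXCL10 had -1.22 in CFPAC and 0.05 in KP3. Cholesterol biosynthesis genes were lower, with a median of -0.15 in each line (camera adjusted p = 0.014, and adjusted p = 0.816 with an estimated correlation). Their members IDI1, an isoprenoid isomerase, had -0.75 and -0.67 and STARD4, a sterol carrier, -0.69 and -0.48. Adjusted over the list alone, 0 genes of each of these 3 lists passed the edgeR test, as over all genes.

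Genes of translation and respiration were also lower as groups with NEK7 siRNA. Cytoplasmic ribosomal protein genes had medians of -0.17 and -0.09, with 43 of 61 lower in both lines (camera adjusted p = 3.35e-05, and adjusted p = 0.816 with an estimated correlation). RPS14 had -1.02 and -0.75 and RPL18 -0.59 and -0.28, while RPL14 had 0.33 and 0.52. Oxidative phosphorylation genes had medians of -0.12 and -0.06 (camera adjusted p = 0.0187, and adjusted p = 0.816 with an estimated correlation), with -0.46 and -0.52 for the respiratory chain subunit COX4I1 and -0.51 and -0.26 for NDUFA1. Mitochondrially encoded genes had medians of -0.24 and -0.06 (camera adjusted p = 0.027, and adjusted p = 0.824 with an estimated correlation), and 10 of 13 were lower in both lines, MT-ND1 by -0.26 and -0.24. Of these 3 lists, 0 genes passed the edgeR test adjusted over the list alone, as over all genes. The NEK kinase family list did not pass (medians 0.02 and 0.05 although the test pointed down, camera adjusted p = 0.774). Of its genes, 2 were lower in the edgeR test adjusted over the list alone and 0 over all genes, NEK7 itself and NEK4, with -0.64 in CFPAC and -0.45 in KP3.

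Several of these list calls rested on 1 library. Without the CFPAC NEK7 siRNA library the camera adjusted p was 0.464 for cholesterol, 0.365 for ribosomal protein, 0.28 for mitochondrially encoded and 0.167 for oxidative phosphorylation genes, and without the KP3 NEK7 siRNA library it was 0.454 for interferon-stimulated, 0.454 for mitochondrially encoded and 0.0912 for oxidative phosphorylation genes. Without the KP3 control library it was 0.725 for interferon-stimulated and 0.167 for cholesterol genes, and without the CFPAC control library 0.959 for mitochondrially encoded and 0.296 for oxidative phosphorylation genes. Mitochondrially encoded genes also lost their call with a pseudocount of 0.1 (0.0901) and among genes with a mean FPKM of at least 5 (0.0793). Hypoxia and glycolysis genes kept their call without any 1 of the 6 libraries.

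None of the inflammasome genes that the series title points to passed the edgeR test with NEK7 siRNA, but neither did any other gene, NEK7 itself included. In simulated counts edgeR found 7 of 201 genes changed 1.5-fold in this contrast, so changes of that size would mostly be missed. PYCARD, the inflammasome adaptor ASC, had log2 differences of 0.15 in CFPAC and 0.56 in KP3, and the inflammatory caspase CASP4 had 0.36 and 0.19. The pore-forming gasdermin GSDMD had 0.24 and 0.15, and its relative GSDME 0.11 and -0.14, on 110 counts in the KP3 control and 37 with NEK7 siRNA (edgeR log2 fold change -0.60). The cytokine IL18 had 0.28 and 0.12, and IL1B had -0.27 and 0.22, on 14 and 57 counts in those KP3 libraries (edgeR log2 fold change 0.54). CASP1, the protease that matures both cytokines, had 0.37 in CFPAC and -0.08 in KP3, where it had 16 counts in the control, 47 in the NEK6 siRNA and 0 in the NEK7 siRNA library. NLRP3 had 377 counts in the CFPAC control and 262 with NEK7 siRNA, a log2 difference of -0.31, and 0 counts in all 3 KP3 libraries. NEK9, the kinase upstream of NEK6 and NEK7, had 0.13 and 0.20. Their edgeR adjusted p-values were 0.554 for CASP4, 0.596 for PYCARD, 0.716 for GSDME and 0.784 for IL1B. The inflammasome and pyroptosis list of 39 measured genes had medians of 0.11 and 0.09 with NEK7 siRNA (camera adjusted p = 0.221) and of 0.14 and 0.00 with NEK6 siRNA (camera adjusted p = 0.73). With either siRNA, 0 of its genes passed the edgeR test adjusted over the list alone, as over all genes.

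The comparison of NEK6 siRNA with control siRNA had AHNAK and LASP1 among its lowest genes and RNAs made by RNA polymerases I and III among its highest. AHNAK, a giant scaffold protein, went from 129884 to 5523 counts in CFPAC and from 119600 to 5250 in KP3, log2 differences of -4.35 and -4.09 (edgeR log2 fold change -4.49, SE 1.34, Benjamini-Hochberg adjusted p = 0.639). Its edgeR log2 fold change ran from -2.98 without the KP3 control to -6.25 without the KP3 NEK6 siRNA library. AHNAK was also at 5336 counts in the KP3 library with NEK7 siRNA but at 155097 in that of CFPAC. LASP1, an actin-binding protein, was lower by -2.20 and -2.57, and in CFPAC it was low with NEK7 siRNA too, at 12.5 FPKM against 48.1 in the control. ZFP36, which destabilizes AU-rich mRNAs, was lower by -1.69 in each line (with NEK7 siRNA -1.73 in CFPAC and -0.33 in KP3), LRP11 by -1.45 and -1.79, KCTD20 by -1.35 and -1.70, ASB1 by -1.23 and -2.04 and the synaptogyrin SYNGR2 by -1.20 and -1.18. The read-through record RNASEK-C17orf49 was lower by -1.35 and -1.38 and overlaps other genes, which makes it uncertain, and SNORD32A was lower by -2.73 and -1.21 on 40 counts or fewer per library in CFPAC control and NEK6 siRNA cells.

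The genes highest with NEK6 siRNA in both lines were mostly RNAs without poly(A) tails. RN7SL1 and RN7SL2, RNA components of the signal recognition particle, were higher by 2.58 and 3.04 in CFPAC and by 3.33 and 2.71 in KP3. For RN7SL2 the edgeR log2 fold change was 2.94 (SE 0.19, Benjamini-Hochberg adjusted p = 0.181). RN7SK, which restrains transcription elongation, was higher by 3.09 and 3.17, and RMRP and RPPH1, RNA parts of the ribonucleases MRP and P, by 3.06 and 2.61 in CFPAC and 4.43 and 2.72 in KP3. The 5.8S ribosomal RNA records RNA5-8SN1, RNA5-8SN2, RNA5-8SN3 and 5_8S_rRNA were higher by 2.5 to 3.0 in CFPAC and by 2.66 to 3.45 in KP3, and reads can be shared among these near-identical copies, as among those of RN7SL1 and RN7SL2. URGCP-MRPS24, a read-through record that overlaps other genes, had 232 and 379 counts with NEK6 siRNA and 0 in the other 4 libraries. No gene passed edgeR's adjusted threshold of 0.05, while 1073 genes had an unadjusted p under 0.05. limma on log2(FPKM + 1) called 0 genes and DESeq2 called 288, of which 138 were higher and 150 lower.

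**Figure D2:**
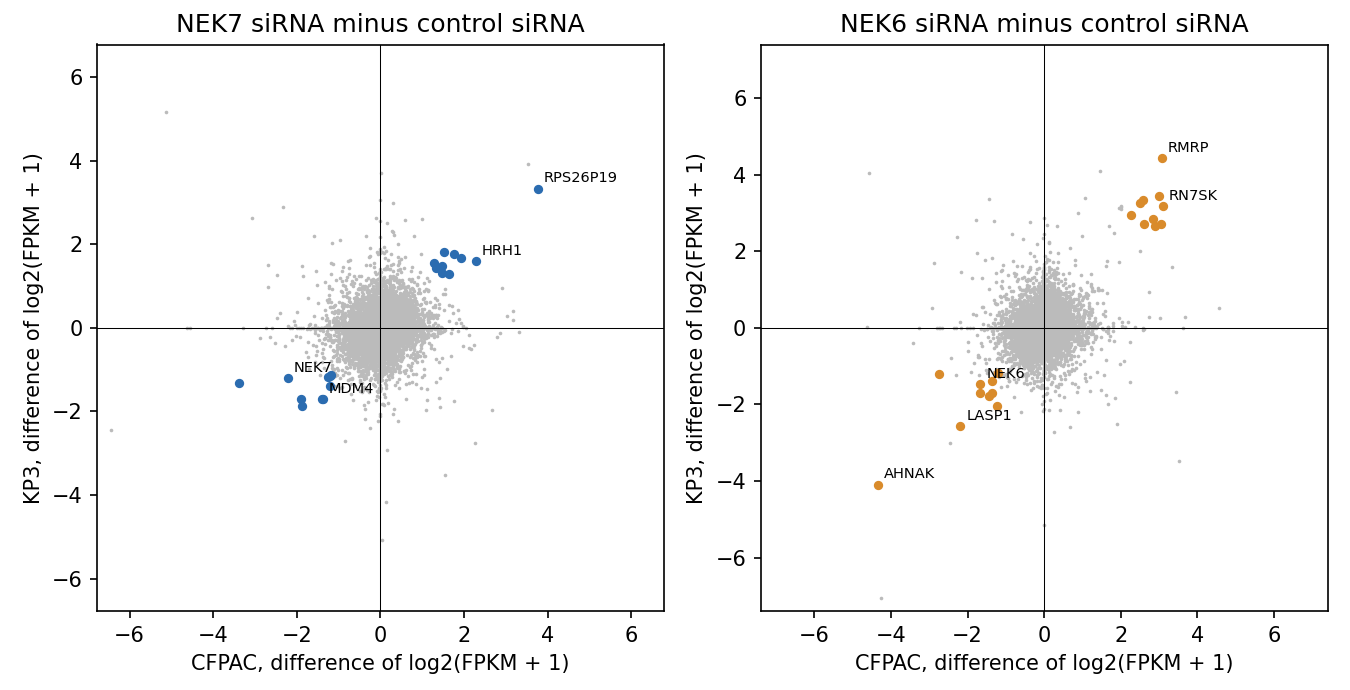
Log2 differences of FPKM + 1 between each siRNA and control siRNA for 14582 genes, CFPAC on the horizontal and KP3 on the vertical axis, with 1 point per gene and some named genes marked. AHNAK lay at -4.35 and -4.09 with NEK6 siRNA, and MDM4 at -1.39 and -1.70 with NEK7 siRNA.

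With NEK6 siRNA, 6 of 31 gene lists were shifted by camera with its preset correlation, 3 up and 3 down, and none with an estimated correlation. Cholesterol biosynthesis genes were lower, with medians of -0.11 in CFPAC and -0.40 in KP3 (camera adjusted p = 7.33e-05, and adjusted p = 0.897 with an estimated correlation). IDI1 had -1.71 and -0.75, the sterol oxidase MSMO1 -0.59 and -0.77, the synthase HMGCS1 -0.51 and -0.51 and the sterol-responsive transcription factor SREBF2 -0.34 and -0.67. Of these 25 genes 2 passed the edgeR test adjusted over the list alone, both lower, and 0 over all genes. Mitosis genes had medians of -0.08 and -0.16 (camera adjusted p = 0.00062, and adjusted p = 0.897 with an estimated correlation), with 25 of 44 lower in both lines, among them the ubiquitin carrier UBE2C (-0.38 and -0.49), the securin PTTG1 (-0.36 and -0.46) and the kinase AURKB (-0.33 and -0.45). DNA replication and S phase genes had medians of -0.05 and -0.11 (camera adjusted p = 0.0121, and adjusted p = 0.897 with an estimated correlation). The ribonucleotide reductase subunit RRM2 had -1.49 and -1.17, the helicase subunit MCM5 -0.46 and -0.94 and the thymidine kinase TK1 -0.49 and -0.65. Adjusted over the list alone, 0 mitosis genes and 1 of the 45 S phase genes passed the edgeR test, and 0 of either over all genes.

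Interferon-stimulated genes were higher with NEK6 siRNA, with medians of 0.11 in CFPAC and 0.33 in KP3 and 30 of 40 higher in both lines (camera adjusted p = 1.46e-06, and adjusted p = 0.897 with an estimated correlation). IFI27 had 1.23 and 1.09, SAMD9 0.94 and 0.28, IFIT1 0.21 and 1.01 and HERC5 0.18 and 0.95. Genes of the basal-like subtype of pancreatic cancer had medians of 0.25 and 0.03 (camera adjusted p = 0.00726, and adjusted p = 0.897 with an estimated correlation), led by the squamous genes SPRR1A (1.21 and 0.33), SPRR1B (1.14 and 0.35) and the keratin KRT6A (1.01 and 0.31). For epithelial and adherens junction genes the test gave a shift up (camera adjusted p = 0.0121, and adjusted p = 0.897 with an estimated correlation), although their median was -0.02 in CFPAC and 0.19 in KP3. The tight junction gene CLDN4 had 4.56 and 0.51, the cadherin CDH1 0.38 and 0.94 and CGN 0.26 and 0.99, while CRB3 had -0.57 and -0.28. Adjusted over the list alone, 1 interferon-stimulated gene passed the edgeR test and 0 genes of the basal-like and epithelial lists, and 0 of any over all genes. Both siRNAs were set against the same control libraries, so part of what their lists share may come from those controls.

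These calls too depended on single libraries. Without the KP3 NEK6 siRNA library the camera adjusted p was 0.201 for cholesterol, 0.177 for mitosis, 0.311 for S phase and 0.293 for epithelial genes, and without the KP3 control library 0.0958 for interferon-stimulated and 0.354 for epithelial genes. Without the CFPAC control library it was 0.126 for S phase and 0.33 for basal-like genes, and without the CFPAC NEK6 siRNA library 0.356 for basal-like genes, which also lost their call among genes with a mean FPKM of at least 5 (0.746).

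**Figure D3:**
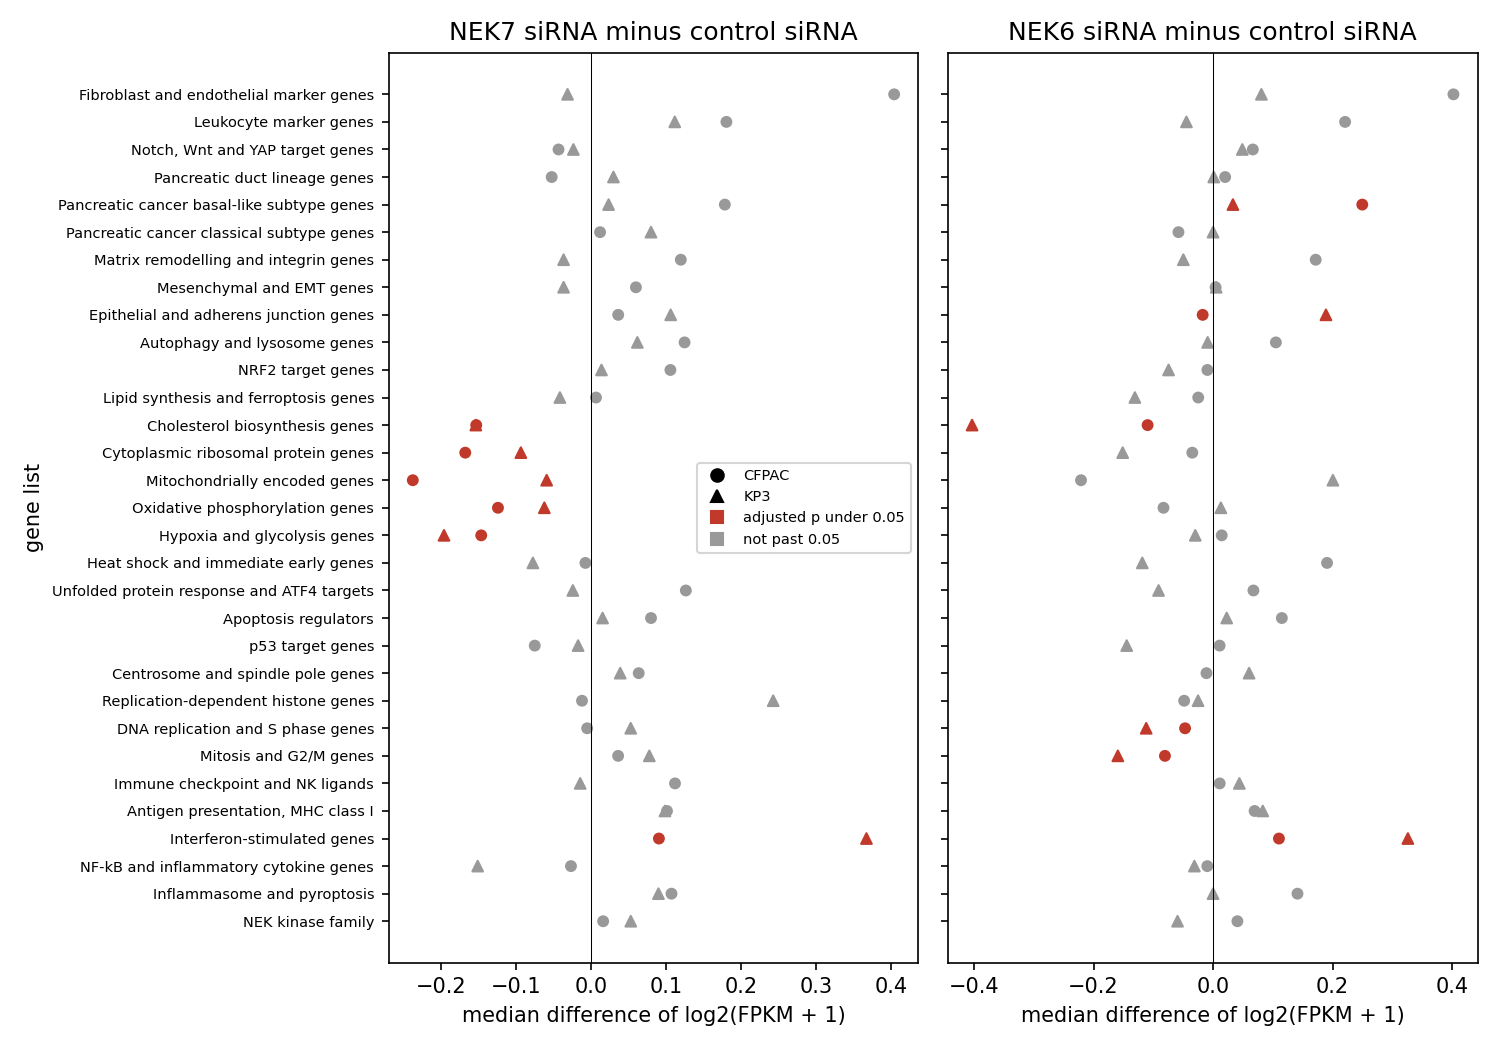
Median difference of log2(FPKM + 1) from control siRNA (horizontal axis) for each gene list (vertical axis), circles for CFPAC and triangles for KP3, in red where camera's adjusted p with the preset correlation was under 0.05. Interferon-stimulated genes had medians of 0.09 and 0.37 with NEK7 siRNA and of 0.11 and 0.33 with NEK6 siRNA.

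In the direct comparison of NEK7 with NEK6 siRNA the log2 differences do not use the control libraries, while the tests take line effect and spread from all 6. Relative to NEK6 siRNA, NEK7 siRNA had higher DAG1, the dystroglycan that links the matrix to the cytoskeleton (log2 differences 1.78 in CFPAC and 3.02 in KP3), SYNGR2 (1.57 and 2.37) and NEK6 itself (1.58 and 1.55). MAFF, a small stress-responsive transcription factor, was lower by -2.06 and -2.43. Against control siRNA, DAG1 had 0.33 with NEK7 and -1.44 with NEK6 siRNA in CFPAC and 2.22 and -0.80 in KP3, and MAFF had -1.93 and 0.13 in CFPAC and -0.21 and 2.22 in KP3. The noncoding RNAs RN7SL2 (-1.98 and -2.10), RNA5-8SN2 (-2.60 and -2.26) and RNA5-8SN3 (-3.24 and -1.95) and the read-through record URGCP-MRPS24 (-2.28 and -2.93) were lower. The pseudogenes RPS26P19 (3.28 and 3.98) and LDHAP4 (1.60 and 1.83) were higher and are uncertain. No gene passed edgeR's adjusted threshold, with 1437 genes at an unadjusted p under 0.05. limma on log2(FPKM + 1) called 0 genes and DESeq2 called 475.

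In that comparison 3 of 31 lists were shifted by camera with the preset correlation. Mitosis genes were higher with NEK7 than with NEK6 siRNA, with medians of 0.09 and 0.24 (camera adjusted p = 0.0358, and adjusted p = 0.96 with an estimated correlation), and the kinesin KIF18A had 0.51 and 0.65, while the phosphatase CDC25B had -0.52 and -0.68. S phase genes had medians of 0.07 and 0.18 (camera adjusted p = 0.0299, and adjusted p = 0.96 with an estimated correlation), with 0.50 and 0.65 for the thymidylate synthase TYMS. Hypoxia and glycolysis genes were lower, with a median of -0.13 in each line (camera adjusted p = 0.0104, and adjusted p = 0.96 with an estimated correlation), and ALDOA had -0.76 and -0.32, although PFKFB3 had 0.15 and 1.04. None of the genes of these 3 lists passed the edgeR test adjusted over the list alone (0 genes), as over all genes. Without the KP3 NEK6 siRNA library the adjusted p was 0.442 for both mitosis and S phase genes, without that of KP3 NEK7 siRNA 0.409 for both, and for mitosis genes it was 0.0678 without the CFPAC and 0.0675 without the KP3 control library. Among genes with a mean FPKM of at least 5 it was 0.111 for mitosis, 0.164 for S phase and 0.0536 for hypoxia genes, and mitosis genes also lost their call with median-ratio rescaling (0.0536) and with camera on the counts (0.0843).

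Within a line, the largest changes were in single transcripts. With NEK7 siRNA, CFPAC cells had higher MLEC, an endoplasmic reticulum lectin (log2 difference 3.16), and MIR22 (3.17), and lower MIR4426 (-4.63) and SNORD22 (-4.55). In these 4 genes the control library stood apart, for MLEC had 2267 counts with control, 17190 with NEK6 and 25767 with NEK7 siRNA, MIR22 1, 74 and 61, and SNORD22 202, 1 and 1. KP3 cells had higher HNRNPH2, an RNA-binding protein (2.98), again with the control apart (1431, 9572 and 12840 counts) and overlapped by RPL36A-HNRNPH2, so that it is uncertain. They also had higher levels of the overlapping record SENP3-EIF4A1 (3.06), and lower SNORA18 (-5.08), AHNAK (-4.18) and SNORD36A (-3.52). With NEK6 siRNA, CLDN4 went from 66 to 9695 counts in CFPAC and from 35 to 191 in KP3, and the MATR3 record ENSG00000280987, 1 of several with that name, was higher by 3.68 in CFPAC. UPK3BL1, which has close copies, was higher by 3.52 in CFPAC and lower by -3.48 in KP3, and SNORD22 was lower by -4.57 in CFPAC and higher by 4.04 in KP3. In KP3 RN7SL3 was higher by 4.10 and RPL36A-HNRNPH2, which overlaps its neighbours, lower by -5.15. MIR4426 was lower by -4.63 in CFPAC with NEK6 siRNA as well, on 123 control counts against 1.

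Counts of genes with at least a 2-fold difference were alike in size for both siRNAs and lines. With NEK7 siRNA 180 genes were higher and 214 lower in CFPAC, and 188 higher and 195 lower in KP3. With NEK6 siRNA the numbers were 189 and 186 in CFPAC and 224 and 184 in KP3, and between NEK7 and NEK6 siRNA 176 and 192 in CFPAC and 232 and 256 in KP3. Genes at least 1.5-fold higher in both lines with NEK7 siRNA numbered 93, where independent lists give 32.3, and 110 were lower in both, where independent lists give 34.4. Another 118 went in opposite directions, where independent lists give 66.6. With NEK6 siRNA 97 were higher in both (26.7 from independent lists), 115 lower in both (30.4) and 120 opposite (57.7), and between NEK7 and NEK6 siRNA 143 were higher (39.3), 131 lower (38.3) and 124 opposite (77.9). Across genes, which are not independent replicates, the differences in CFPAC and KP3 had Pearson's r of 0.164 and Spearman's rho of 0.267 for NEK7 siRNA, 0.170 and 0.186 for NEK6 siRNA and 0.193 and 0.240 between the siRNAs. NEK6 siRNA in CFPAC against NEK7 siRNA in KP3 gave r = 0.102, and NEK7 siRNA in CFPAC against NEK6 siRNA in KP3 gave r = 0.0274. Within a line both siRNAs share a control library, and there r was 0.512 in CFPAC and 0.415 in KP3, beside 0.499 and 0.498 in 20 simulations of unchanged groups. The covariance was 0.0787 in CFPAC against 0.0746 simulated, and 0.0651 in KP3 against 0.0744 simulated.

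The lines themselves differed far more than any siRNA condition. Of the genes highest in CFPAC, TFF3, a trefoil mucosal peptide, was at least 749-fold higher, FBP1, a gluconeogenic enzyme, at least 722-fold, ANXA13 at least 936-fold and the xenobiotic receptor NR1I2 at least 795-fold, each at 0 counts in all 3 KP3 libraries. The same held for the glucuronosyltransferase UGT1A10 (at least 2135-fold), the placental phosphatase ALPP (at least 1641-fold), the R-spondin receptor LGR6 (at least 1558-fold), the potassium channel KCNQ3 (at least 1422-fold), MDGA1 (at least 1116-fold), the MHC class II gene HLA-DQB1 (at least 1098-fold), the long noncoding RNA LINC01133 (at least 1052-fold) and IDO1, which degrades tryptophan (at least 829.7-fold). At 0 counts in CFPAC were SALL1, EYA1 and TFAP2C, which act in transcription in development, at least 706-fold, 702-fold and 518-fold lower than in KP3. The others were FAM153A (at least 546-fold), TARID (at least 526-fold), CA8 (at least 474-fold), KIRREL2 (at least 405-fold), ANKRD35 (at least 320.2-fold), SLAIN1 (at least 314-fold), ZNF18 (at least 312-fold), MIR4458HG (at least 268-fold) and ZNF880 (at least 265-fold). The folds are set against a floor of 3 counts per library, and the edgeR adjusted p-values of these 24 genes ran from 0.00036 to 0.00141. UGT1A10 shares exons with its gene cluster and ALPP and FAM153A have close copies, so their reads are uncertain.

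In all, 8223 of 14582 genes passed the edgeR quasi-likelihood test between the lines at a Benjamini-Hochberg adjusted p under 0.05, with 4277 higher and 3946 lower in CFPAC. Of these, 2592 were at least 2-fold higher and 2144 at least 2-fold lower. The libraries of a line had different siRNAs and are not independent samples of that line.

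Inflammasome genes were among those that parted the lines. NLRP3 was at 377, 418 and 262 counts in the CFPAC control, NEK6 siRNA and NEK7 siRNA libraries and at 0 in KP3, at least 119.6-fold higher (edgeR adjusted p = 0.00276). IL1B was higher in CFPAC by a log2 fold change of 7.45 (SE 0.57, edgeR adjusted p = 0.000625), CASP1 by 6.27 (SE 0.99, adjusted p = 0.0051 by edgeR), GSDME by 3.47 (SE 0.44, adjusted p = 0.0026 by edgeR) and IL18 by 0.77 (SE 0.12, adjusted p = 0.00542 by edgeR). PYCARD (0.00, SE 0.16), CASP4 (0.16, SE 0.09) and GSDMD (-0.09, SE 0.12) did not pass, nor did NEK7 (-0.18, SE 0.36) and NEK9 (0.14, SE 0.10), with edgeR adjusted p-values of 0.983, 0.207, 0.559, 0.698 and 0.265. Without 1 library these calls stayed past the threshold, and the log2 fold change of CASP1 ran from 5.37 (without the KP3 NEK7 siRNA library) to 7.35 (without that of CFPAC NEK6 siRNA). NEK6 was lower in CFPAC, by -0.59 (SE 0.11, edgeR adjusted p = 0.00772). Of the 39 measured genes of the inflammasome and pyroptosis list 20 were higher and 5 lower in CFPAC, as many adjusted over the list alone (camera adjusted p = 0.0476, and adjusted p = 0.624 with an estimated correlation). The list's call was lost without the CFPAC NEK6 siRNA library (0.0842), without the KP3 NEK6 siRNA library (0.0836), among genes with a mean FPKM of at least 5 (0.556) and with camera on the counts (0.192).

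**Figure D4:**
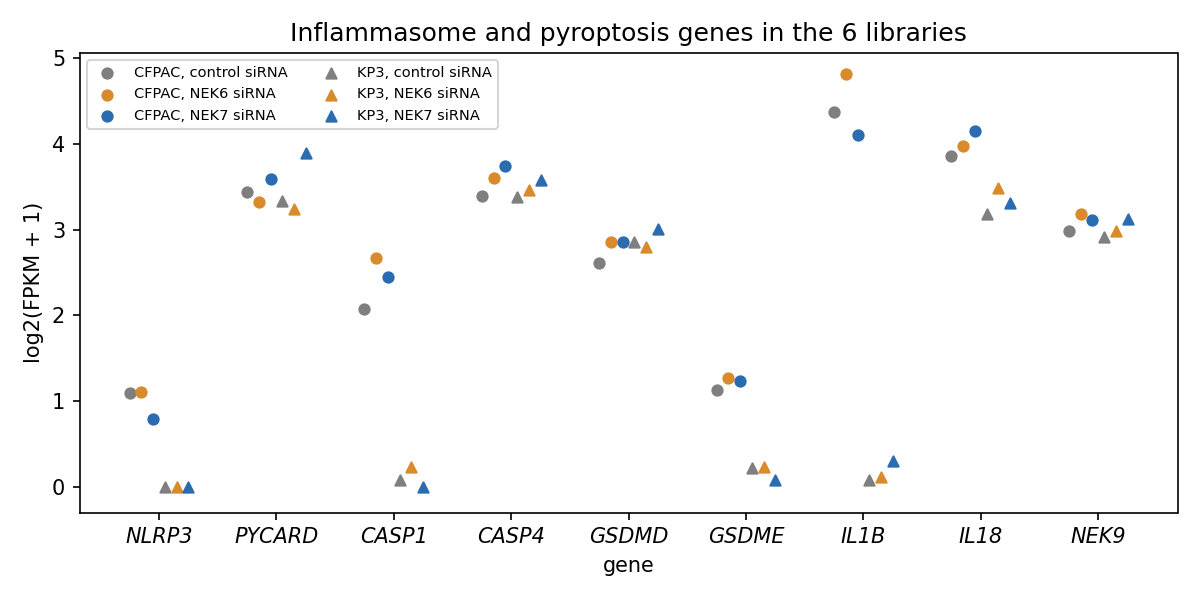
Expression as log2(FPKM + 1) (vertical axis) of inflammasome and pyroptosis genes (horizontal axis) in the 6 libraries, circles for CFPAC and triangles for KP3, coloured by siRNA. NLRP3 was at 0 in KP3, while PYCARD had 9.84 FPKM in CFPAC and 9.07 in KP3 with control siRNA.

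Interferon-stimulated genes were the list most evenly raised in CFPAC, where 38 of 40 were higher and 1 lower, as many adjusted over the list alone (camera adjusted p = 2.11e-14, and adjusted p = 0.597 with an estimated correlation). OAS2, an antiviral synthetase, was higher by 7.31, RSAD2 by 6.73, SAMD9L by 6.89 and CXCL10 by 6.37. S phase genes were higher in 40 of 45 cases and lower in 2, as many adjusted over the list alone, with CCNE2, a cyclin of the G1/S transition, at 3.93 and the sliding clamp PCNA at 2.55 (camera adjusted p = 5.85e-09, and adjusted p = 0.597 with an estimated correlation). Of 24 NRF2 target genes 17 were higher and 4 lower, as many adjusted over the list alone, and the detoxifying reductases AKR1B10 and AKR1C2 stood at 11.36 and 9.26 and the dehydrogenase ALDH3A1 at 5.81 (camera adjusted p = 0.00102, and adjusted p = 0.597 with an estimated correlation). Genes of the classical subtype of pancreatic cancer were higher in 18 of 25 cases and lower in 2, with 18 and 3 adjusted over the list alone, among them TFF3 and the intestinal cadherin CDH17 at 8.83 (camera adjusted p = 4.95e-05, and adjusted p = 0.597 with an estimated correlation).

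Cholesterol biosynthesis genes were lower in CFPAC in 23 of 25 cases and higher in 2, as many adjusted over the list alone (camera adjusted p = 7.08e-07, and adjusted p = 0.597 with an estimated correlation). INSIG1, a sterol-regulated brake on the pathway, had -3.52, TM7SF2 -2.73 and HSD17B7 -2.70. Cytoplasmic ribosomal protein genes were lower in 31 of 61 cases and higher in 1, as many adjusted over the list alone, with RPS6 at -1.53 and RPL13 at -1.40 (camera adjusted p = 4.95e-05, and adjusted p = 0.706 with an estimated correlation). Mitochondrially encoded genes were higher in 11 of 13 cases and lower in 1, with 11 and 2 adjusted over the list alone, MT-ND3 by 1.19 and MT-CO3 by 1.11 (camera adjusted p = 0.00966, and adjusted p = 0.706 with an estimated correlation). This list's call was lost without the CFPAC NEK7 siRNA library (0.0522) and with camera on the counts (0.0519).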

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

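The tests of the seed, base composition, kinase loss, library scaling, NEK6 loss, jumping genes and splits of the libraries were chosen only after the results were seen, while that of carried-over RNA was chosen before. Mitochondrially encoded genes stood out because their list moved in opposite directions in the lines with NEK6 siRNA. Their median log2 difference was -0.22 in CFPAC, at the 0.515th percentile of matched random lists, and 0.20 in KP3, at the 99.6th, so that KP3 minus CFPAC was 0.42. The difference was not tested, and no explanation of it was tested.

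Part of the genes lower with an siRNA in both lines shared a word in their 3' UTRs, for in CFPAC the 7-base word of lowest z was GTTAATA with NEK7 siRNA (z = -15.7) and TGCCTCA with NEK6 siRNA (z = -11.0), and in KP3 the same words had z = -6.57 and z = -7.37, the lowest of 140 and of 420 words of their base composition and the 38th and 1st of all 16335. The next lowest words in CFPAC had z = -7.07 and -10.1, and the lowest other words of the same composition in KP3 had -0.16 and -6.71, the latter ATGCCTC, which is TGCCTCA shifted by a base. Base composition of the 3' UTR as the whole cause is argued against in KP3, since both words lay at least 6.66 SD below the median of the other words. A seed match of the NEK7 siRNA may thus account for part of the genes lower with it. GTTAATA occurs once in the NEK7 mRNA. That is weak evidence, since TTAATAT, with z = 3.79 in KP3, occurs there 3 times, while TTAATAC (z = 1.49) occurs 0 times. For the NEK6 siRNA a seed match stays open, since TGCCTCA and its reverse complement occur 0 times in the NEK6 mRNA. Of the words shifted by a base added before, the reverse complement occurs there 1 time for ATGCCTC, 2 for CTGCCTC and 0 for GTGCCTC and TTGCCTC. The siRNA sequences are not given in the sources used here. Of the named lower genes searched, MDM4 held 1 GTTAATA site, and NEK7, GPD1L, KCTD20 and SCAMP1 held 0. AHNAK, LASP1, ASB1 and SYNGR2 held 1 TGCCTCA site each and LRP11 held 2, while ZFP36, NEK6, RNASEK-C17orf49 and KCTD20 held 0. Loss of the kinase itself stays open for the 67 genes lower in both lines without the word, since each siRNA had 1 library per line. They were 27 of 51 searched with NEK7 siRNA (7.05 from independent lists) and 40 of 81 with NEK6 siRNA (7.62). Genes without the word that went in opposite directions also exceeded independent lists, with 42 against 21.6 for NEK7 and 31 against 15.4 for NEK6 siRNA.

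The 9 named RNAs without poly(A) tails were higher in the NEK6 siRNA libraries, with medians of 2.89 in CFPAC and 3.17 in KP3, and had 0.29 and 1.01 with NEK7 siRNA. They were named for their rise with NEK6 siRNA, so high medians with it follow from the selection. Scaling of the libraries is argued against, since the lower of both medians after median-ratio rescaling was 2.91. Carry-over of such RNA could not be decided, because 11 other such RNAs had at most 6.81 FPKM, with medians at the 55.6th percentile of matched random lists in CFPAC and at the 100th in KP3. Loss of NEK6 itself also stays open. The medians of the 9 named exceeded those with NEK7 siRNA by at least 2.16, but the selection favours such an excess, and each line had 1 library per siRNA.

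Among 21 jumps of at least 8-fold between libraries of a line, in genes reaching 5000 counts, were CLDN4 in CFPAC (807-fold) and AHNAK (28.1-fold in CFPAC, 23.0-fold in KP3). A response to the siRNA common to both lines stays open, with 1 library per line and siRNA. For 6 of the jumps (CLDN4, RN7SL1 and 2 records each of FP236383 and FP671120) the NEK6 siRNA library stood at least 2-fold above both others in the other line too. RN7SL1 is 1 of the 9 RNAs above, so carry-over cannot be told apart there, and the FP236383 and FP671120 records were not part of that test. For the other jumps, such as DAG1 and MLEC, the same library did not stand so far apart the same way. AHNAK missed this rule because in KP3 it was low with both siRNAs (5476 normalized counts with NEK6 and 5098 with NEK7 siRNA, 117371 in the control). In CFPAC it had 5430 with NEK6 siRNA and 137845 in the control. The search for overlapping records covered the same strand and shared names, not the other strand or near-identical copies such as RN7SL2 for RN7SL1. Within that limit, reads moving between overlapping gene records cannot account for the 10 jumps of genes with no such record, among them CLDN4, AHNAK, MLEC and TRIM56. Reads moving also cannot account for 6 jumps of genes with such a record, as the sum over records also varied at least 8-fold (MRNIP, AC011603 and 2 records each of FP236383 and FP671120). Of the other 5, both MATR3 records traded counts in CFPAC. With control, NEK6 and NEK7 siRNA, 1 had 11450, 1428 and 16300 normalized counts and the other 582, 13006 and 110. Their sum varied at most 1.36-fold, which argues against a real change of MATR3 as a whole, and reads moving may account for both jumps. For AC138811, RAB43 and HNRNPH2 reads moving cannot be told apart from a real change, as that sum varied 1.13-fold, 2.68-fold and 4.01-fold. Other steps of the authors' counting were not tested.

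The count of 8223 genes past the threshold between the lines was set against other splits of the 6 libraries into 3 and 3. There are 10 splits, of which 1, the real one, gave as many, and the highest of the others gave 0. Every other split mixed libraries of both lines, so the line difference entered its spread and counts near 0 were to be expected. The splits therefore cannot back the count, and they are also too few for a share under 0.05.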

How the results depend on the processing

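The tests with DESeq2, limma itself, DESeq2 size factors, filterByExpr, protein-coding genes and camera on the counts were chosen after seeing the data, and the cause of the moves below was not tested unless given. edgeR called 0 genes in each siRNA contrast (unadjusted p under 0.05 in 1372 for NEK7, 1073 for NEK6 and 1437 for NEK7 against NEK6 siRNA), as did every limma and edgeR alternative with all 6 libraries, while DESeq2 called 369, 288 and 475. Without 1 library the counts ran from 0 to 1 for NEK7, were 0 for NEK6 and ran from 0 to 1 for NEK7 against NEK6 siRNA. The 1 gene came without the CFPAC NEK7 siRNA library, a clone record, AC012321, looked up after its call was seen. Between the lines, 4122 genes passed with a mean FPKM of at least 5, where fewer genes (6341) were tested, 7269 to 9216 under the other settings with all libraries, and 6422 to 6529 without 1 library.

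Counts of genes at least 2-fold different within a line rose with a pseudocount of 0.1, which widens differences near 0, to 1204 in CFPAC and 1217 in KP3 for NEK7, 1164 and 1151 for NEK6, and 1211 and 1376 for NEK7 against NEK6 siRNA, and those at least 1.5-fold different in both lines to 679, 599 and 759. With a mean FPKM of at least 5, which leaves fewer genes, they were 134 and 150, 146 and 168, 149 and 202, with 96, 120 and 146 in both lines. With protein-coding genes they were 207 and 210, 192 and 217, 190 and 259, with 117, 129 and 171.

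With an estimated correlation 0 lists passed in each of the 4 contrasts, but with 2 residual degrees of freedom that setting could hardly call any list. Where the estimate lay far above the preset 0.01, as for mitochondrially encoded genes (0.871), the preset calls may be too strong. Without 1 library 3 to 7 lists passed for NEK7, 3 to 7 for NEK6 and 2 to 5 for NEK7 against NEK6 siRNA, where also 0 passed with a mean FPKM of at least 5 and 5 with camera on the counts. Of list calls, 81 kept their side of the threshold and 34 lost it under other settings, and 109 and 29 without 1 library, all with the same direction.

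Of single genes, 308 values kept direction and side under 3 limma settings (a pseudocount of 0.1, median-ratio rescaling and quantile normalization) and 7 turned, whereas DESeq2 called 15 of 39 named genes for NEK7, 18 of 37 for NEK6 and 10 of 20 for NEK7 against NEK6 siRNA, where edgeR called 0. CASP1 with NEK7 siRNA was -0.29 by edgeR, 0.132 by limma with median-ratio rescaling and 0.0818 with quantile normalization, and IL1B was 0.54, -0.0416 and -0.0235. PYCARD between the lines was 0.00 by edgeR and, by limma, -0.0392 with a pseudocount of 0.1, -0.0096 with median-ratio rescaling and -0.073 with quantile normalization. Without 1 library 611 kept and 19 turned. With NEK7 siRNA the ranges were -0.17 to 0.0767 for NEK6, -0.69 to 0.0112 for NLRP3, -7.28 to 0.58 for CASP1, -1.59 to 0.11 for GSDME and -0.32 to 1.93 for IL1B. With NEK6 siRNA they were -0.60 to 0.56 for NEK7, -0.31 to 0.33 for NLRP3, -0.23 to 0.0151 for PYCARD, -0.0341 to 0.26 for GSDMD, -0.24 to 0.68 for GSDME and -0.44 to 1.42 for IL1B. Between the lines they were -0.58 to 0.33 for NEK7 and -0.0791 to 0.15 for PYCARD. All values that turned, under other settings or without 1 library, belonged to the genes always named. The other genes were picked for large changes alike in both lines or large differences between the lines, so few could turn. No gene passed edgeR in an siRNA contrast, so keeping its side of the threshold there says little. The siRNA contrasts were paired by cell line as the block, and without it edgeR also called 0 genes, with an unadjusted p under 0.05 in 79, 114 and 143. Depth limits genes near 0 counts, such as CASP1 in KP3 (16, 47 and 0 counts).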
